A study of Mus musculus with 12 samples.

How the data were processed

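RNA was measured by sequencing in 12 mouse libraries, 3 for each of 4 groups, after 24 h. The groups are PBS and NP@M, both without D, and NP-D@MP and NP-D@M, both with D. Per the labels the cells are immune cells from marrow with the cell line name TAMC, while the extraction protocol in the same records speaks of retinas. The labels do not resolve this conflict. In the values, 6 markers of neutrophils and granulocyte precursors had means of at least 50 FPKM over all libraries, and no retina marker was testable. This argues against retina as the source, although how genes were picked for the table is not stated. The labels say that libraries were made from total RNA with an Illumina TruSeq kit and standard protocols. Nothing in the labels says whether the 3 libraries of a group come from separate cultures or animals, so the p-values measure only the spread between these libraries.

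The FPKM values used are those the authors deposited, in 1 table of 11669 genes. The table's header does not name the unit, which was read from the values. Each value multiplied by the gene length in the table is a whole multiple of 1 step per library, within 0.05 of a whole number for 100% of the values, so that read counts were recovered. The step corresponds to a library size of 31.6 M to 38.1 M without D and 7.84 M to 8.87 M with D, against recovered reads of 14444950 to 17338264, so a factor between libraries had been applied by the authors, by a method the labels do not state. The submitters' processing notes name Bowtie 0.12.2 and the build mm8 without their role. Gene identifiers in the table matched GENCODE release M21 on GRCm38 for 11665 genes and coordinates were equal for 11219, so positions are given on GRCm38. How genes were picked for the table is not stated. The log2 fold changes leave a gap around 0 in the comparisons of D with no D, as a table picked for differences would, and p-values there hold only within the table. Floors for a count of 0 (3 reads) cover counting error only, since reads without molecular identifiers are not independent molecules. Reads within groups varied by more than counting error.

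Genes with a value of at least 1 in at least 3 libraries were tested, 8615 in all. Log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 with 4 group means over all 12 libraries, with the trend and robust options of its empirical Bayes step. Tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes of each of 5 comparisons, and genes with an adjusted p under 0.05 were called. The pseudocount of 1 understates fold changes of genes with low values. Gene lists, 31 in number, cover the cell cycle, CDKs, p53 targets, stress, apoptosis, inflammation, antigen presentation, metabolism, ribosomes, mitochondria and cell type markers. Of these, 24 had at least 5 tested members and were compared with all other tested genes by camera in limma, with its preset correlation of 0.01 between genes, and adjusted over the 24 lists of a comparison. The other 7 were too small, and 2 of them, the T and NK cell and the retina markers, had 0 tested members. Called members were counted over all genes and adjusted over the list alone. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 read the table and drew the plots.

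Groups, comparisons, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names, for each comparison, up to 8 called genes in each direction with the largest fold change (5 in the comparisons of D groups with PBS). They need a proper gene symbol, groups that do not overlap and a mean of at least 5 FPKM in the higher group. It also names up to 3 members with the smallest adjusted p of each list that passed camera or had a called member, and Cd274, Pdcd1lg2, Cdk1, Cdk2, Cdk5, Cdk9, Cdkn1a, Irf1, Irf2bp2, Myc and Mcl1 whatever their values. Some results that the rule names are not reported here. List members are named gene by gene in the first 3 comparisons only. Gm24366 and Il1b were named after their values were seen.

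The procedure was tested on simulated data with the same layout, with 9327 tested genes and a dispersion of 0.04. Of the genes changed 2-fold it recovered 80.6%, of those changed 4-fold 100%, with 7 false calls in the simulated NP-D@M against NP@M, 1 in NP@M against PBS, and calls for 0 of 40 lists without a shift. Only 98 and 100 tested genes had been changed by these folds. The simulation had no factor between libraries, no library unlike its group mates and genes drawn independently. These rates therefore do not carry over to the deposited data, least of all those for lists.

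Alternatives set beforehand were quantile normalization, equal medians, no filter on low values, a filter of 5 in 3 libraries, limma without trend, a pseudocount of 0.1, a fit of the 6 libraries compared alone, a fold threshold of 1 on the log2 scale, leaving out each library in turn and, for lists, an estimated correlation between genes. Added after seeing the data were 5 more, scaling to the recovered read totals, removal of each library's trend on gene length or on GC content (lowess span 0.3), voom on the recovered reads, and leaving out PBS replicate 3 and NP@M replicate 2 together. The voom fit used the library sizes that the deposited values imply, so it keeps the authors' factor between libraries and does not test it. Transcription factor genes were compared with 10000 random sets matched on length and level.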

Results

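RNA was sequenced from 12 mouse libraries of TAMC, a name given under the cell line tag for immune cells whose tissue is marrow. Cells had been exposed for 24 h to PBS, NP@M, NP-D@M or NP-D@MP, and each of these 4 groups held 3 libraries. The series concerns nanodrugs that carry a cancer cell membrane and are aimed at cyclin-dependent kinases (CDKs), used with an antibody against PD-L1. The labels do not spell out TAMC, NP, D, M or P, so the names are kept as given. The FPKM table held 11669 genes, and the reads recovered from it came to 15.9 M ± 0.924 per library (SD, n = 12), from 14444950 in PBS replicate 3 to 17338264 in NP-D@MP replicate 1.

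Libraries with D differed in make-up from those without. Shares of reads given here are shares of the recovered reads. These cover only the genes of the table, which appears picked for differences, and not whole libraries. The read totals used for scaling are sums over the same genes. The 10 most abundant genes took 11.6% ± 0.775 of the reads (SD, n = 6) without D and 34.5% ± 0.688 with D. Fth1, which encodes the ferritin heavy chain and has processed pseudogenes that can share its reads, took 2.78% ± 0.890 of the reads (SD, n = 6) without D and 9.51% ± 0.554 with D. Mitochondrially encoded genes held 0.893% ± 0.107 of the reads in PBS (SD, n = 3), 0.854% ± 0.0881 in NP@M, 1.89% ± 0.137 in NP-D@M and 1.93% ± 1.10 in NP-D@MP, where replicate 1 alone reached 3.17%. The library size that the deposited values had been divided by was 2.32 ± 0.0635 times the recovered reads (SD, n = 6) without D and 0.504 ± 0.0316 times with D. Changing from that scaling to the recovered read totals moves every gene by -2.17 on the log2 scale in NP-D@M against NP@M, before the pseudocount. PBS replicate 3 and NP@M replicate 2 stood apart from their groups, with 9.31% and 9.11% of the genes at 0 against 2.65% to 2.96% in the other libraries without D. The correlation across genes between these libraries and their group mates was 0.832 to 0.906, against 0.978 to 0.993 for the other pairs within groups, and genes are not independent replicates.

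**Figure D1:**
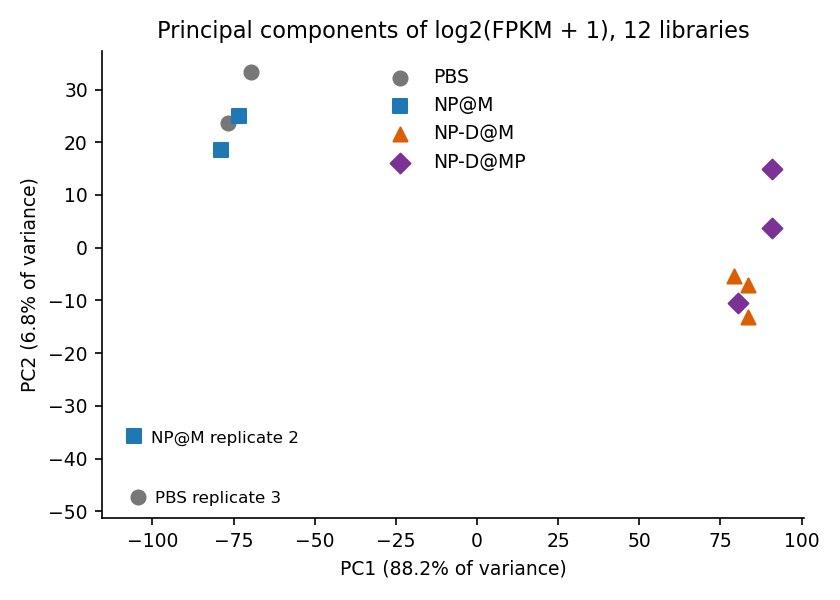
Principal components of log2(FPKM + 1) in the 12 libraries, with each point 1 library and each axis 1 component with its share of the variance. The first component, 88.2% of the variance, parts the libraries with D from those without, and PBS replicate 3 and NP@M replicate 2 lie lowest on the second, which holds 6.79%.

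The comparison of NP@M with PBS asks how NP@M, which has no D in its name, differs from the vehicle. Its single called gene was Gm24366 (ENSMUSG00000093124), a microRNA gene of 86 bp on chromosome 8 from 122471627 to 122471712, which was named after its values were seen. Gm24366 had 1, 1 and 0 reads in the PBS libraries and 5, 12 and 10 in the NP@M libraries, a log2 fold change of 1.65 (SE 0.20, adjusted p = 0.0459 by limma, higher in 3 of 3 libraries). Cd274, which encodes PD-L1, stood at 84.7 FPKM ± 32.0 in PBS and 83.7 ± 23 in NP@M (SD, n = 3), a log2 fold change of 0.02 (SE 0.26, adjusted p = 1). Fos, an immediate early transcription factor, stood at 61.4 FPKM ± 10.6 in PBS and 27.8 ± 5.32 in NP@M (SD, n = 3). Its log2 fold change was -1.12 (SE 0.27, adjusted p = 1), lower in 3 of 3 libraries and not called.

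Of the 24 gene lists tested, 4 passed camera in this comparison with its preset correlation, and 0 held with an estimated one. Type I interferon response genes were lower with a median log2 fold change of -0.18 over 13 members (adjusted p = 0.00136, and adjusted p = 0.391 with an estimated correlation), with Irf7, a transcription factor of that response, at -0.57. Immediate early genes were lower with a median of -0.08 over 17 members (adjusted p = 0.0102, and adjusted p = 0.68 with an estimated correlation). NF-kB and inflammatory cytokine genes were higher with a median of 0.09 over 19 members (adjusted p = 0.00655, and adjusted p = 0.596 with an estimated correlation). Integrated stress and unfolded protein response genes were higher with a median of 0.13 over 13 members, with Xbp1, a transcription factor of the unfolded protein response, at 0.23 (adjusted p = 0.00655 for the list, and adjusted p = 0.391 with an estimated correlation). Members of these 4 lists with a call over all genes numbered 0, and adjusted over the list alone 1 immediate early gene was lower. Without PBS replicate 3, the adjusted p was 0.854 for the interferon list, 0.831 for the NF-kB list and 0.854 for the stress list. Without PBS replicate 1 and replicate 2 in turn it was 0.417 and 0.505 for the immediate early list, whose direction turned without NP@M replicate 2 (adjusted p = 1). Over all alternatives the adjusted p ran from 3.08e-05 to 0.854 for the interferon list, from 3.08e-05 to 0.831 for the NF-kB list, from 0.000583 to 0.854 for the stress list and from 0.000814 to 1 for the immediate early list. Lists that gained a call were also seen. Ribosomal protein genes were lower without PBS replicate 3 (2.28e-05), without NP@M replicate 1 (0.0189) and without both libraries that stood apart (1.04e-05), and monocyte and macrophage markers without PBS replicate 2 (0.0248) or NP@M replicate 1 (0.0189). MHC class I genes were lower without PBS replicate 3 (0.047) and granulocyte markers without NP@M replicate 3 (0.0234). Without both libraries that stood apart, G2/M (0.0352) and lysosome (0.0412) genes were higher and glycolysis genes lower (0.0412). The NF-kB list also lost its call without PBS replicate 1 (0.227), NP@M replicate 1 (0.0542) or NP@M replicate 2 (0.154), and the stress list without NP@M replicate 1 (0.153) or replicate 3 (0.142).

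By limma, 1 of 8615 tested genes was called and 27 had an unadjusted p under 0.05, fewer than chance gives at that threshold. Voom on the recovered reads called 0. The groups did not overlap in 248 genes (2.88%, where chance gives 10%). PBS replicate 3 and NP@M replicate 2 stood apart from their mates in these groups, so the few calls do not show that NP@M changed nothing. The call of Gm24366 rests on 12 reads or fewer per library, and over the alternatives its log2 fold change was 1.32 to 3.44 with an adjusted p from 0.00126 to 1. It held with the fold threshold of 1 on the log2 scale, with the read totals (0.0431) and without NP@M replicate 1 (0.00126). The call ended without PBS replicate 1 (0.150), PBS replicate 2 (0.213), PBS replicate 3 (0.179), NP@M replicate 2 (0.089) or NP@M replicate 3 (0.349). It also ended under each of the other settings that gave Gm24366 a value.

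The comparison of NP-D@M with NP@M asks what differs with D in the name, and here most genes of the table differed. The steepest fall was in Dusp6 (ENSMUSG00000019960, chromosome 10 from 99263231 to 99267489), a phosphatase that switches off ERK, which went from 50 FPKM ± 9.08 to 0.172 ± 0.105 (SD, n = 3), a log2 fold change of -5.43 (SE 0.21, adjusted p = 4.88e-08 by limma, lower in 3 of 3 libraries). The pseudocount of 1 holds such a fold change in, as for other genes near 0 in 1 group. Sgk1, a kinase, changed by -5.11, and Fpr1, the receptor for formylated bacterial peptides, by -4.95. Trib3, induced by the integrated stress response, changed by -4.73, and Ptafr, the receptor for platelet-activating factor, by -4.57. Tor4a changed by -4.47, and the transcription factors Xbp1 and Ets2 by -4.45 and -4.44.

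Ccl12 (ENSMUSG00000035352, chromosome 11 from 82101845 to 82103400), a monocyte-attracting chemokine with close paralogs, rose from 5.43 FPKM ± 3.19 to 312 ± 73.8 (SD, n = 3), a log2 fold change of 5.73 (SE 0.41, adjusted p = 3.8e-07). Pf4, platelet factor 4, rose by 4.96 from 718 FPKM to 19753 FPKM, and Npy, neuropeptide Y, by 5.03. Fabp5, a fatty acid carrier, rose by 4.53 (3.90 without NP@M replicate 2) and S100a1, a calcium-binding protein, by 4.51. The small non-coding RNA gene Rn7sk, whose RNA holds the kinase complex P-TEFb inactive, rose by 6.87 (SE 0.46, adjusted p = 2.64e-07), and Snora17 by 4.51 (SE 1.02). Snora17 stood at 48.5 FPKM ± 62.6 in NP-D@M (SD, n = 3) and changed by 5.46 without NP-D@M replicate 2 and by 3.38 without NP-D@M replicate 3. Rnu5g, a spliceosomal RNA gene, had 0 reads in every NP@M library and was at least 29.1-fold higher in NP-D@M with the deposited scaling and 6.46-fold with the read totals, against a floor of 3 reads per library. These small RNA genes have related copies in the genome that can share reads. After scaling to the read totals, the 8 named genes that rose stayed higher, with Ccl12 at 3.75, Pf4 at 2.80 and Rn7sk at 5.78, and the 8 that fell stayed lower, with Dusp6 at -6.74.

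**Figure D2:**
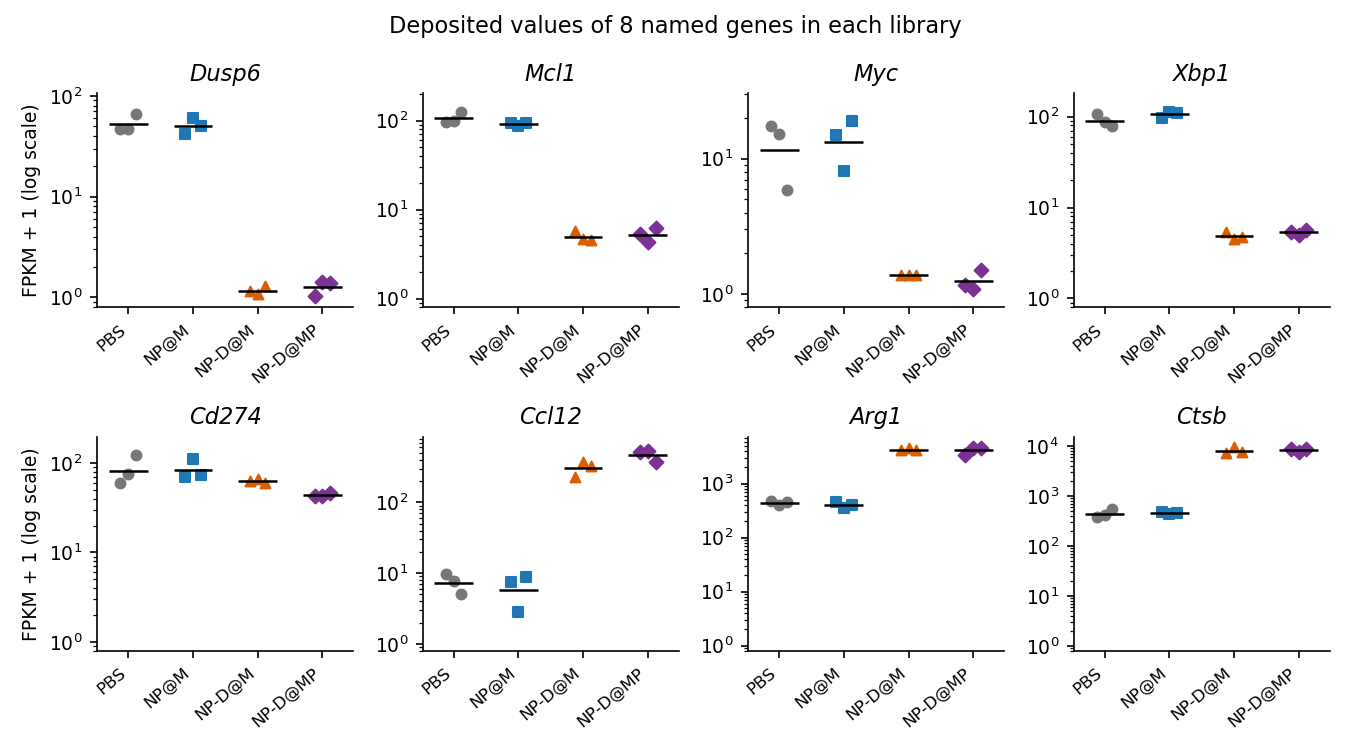
Deposited values of 8 named genes in each of the 12 libraries, as FPKM + 1 on a log scale, with points for libraries and a bar for each group's mean. Dusp6, Mcl1, Myc and Xbp1 lie lower in all 6 libraries with D and Ccl12, Arg1 and Ctsb higher, while Cd274 differed by -0.40 between NP-D@M and NP@M, which did not pass the test as deposited.

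Among the genes fixed for their link to CDKs and PD-L1, Mcl1, a short-lived survival factor of the BCL2 family, fell from 91.6 FPKM ± 4.17 to 4 ± 0.704 (SD, n = 3), a log2 fold change of -4.22 (SE 0.19, adjusted p = 7.23e-08). Myc, a transcription factor for growth, fell from 13.0 FPKM ± 5.46 to 0.377 ± 0.00519 (log2 fold change -3.26, adjusted p = 1.75e-05). Cdkn1a, an inhibitor of CDKs, fell with a log2 fold change of -2.87, the corepressor Irf2bp2 with -2.58, the interferon regulator Irf1 with -2.34 and Pdcd1lg2, which encodes PD-L2, with -1.68. Cdk5 rose by 2.16 with the deposited scaling, and stood at 0.22 with the read totals (adjusted p = 0.436, with a range from 1.19e-06 to 0.436 over the alternatives). The mitotic kinase gene Cdk1 rose by 0.61 (adjusted p = 0.00519) as deposited and turned to -1 with the read totals. Cd274 (ENSMUSG00000016496, chromosome 19 from 29367455 to 29388095) stood at 83.7 FPKM ± 23 in NP@M and 61.8 ± 3.39 in NP-D@M (SD, n = 3). Its log2 fold change of -0.40 (SE 0.26, adjusted p = 0.16) did not pass the test as deposited, and lay between -2.54 with the read totals (adjusted p = 2.51e-06) and 0.13 with equal medians (adjusted p = 0.66). Quantile normalization gave -2.43 for Cd274 (adjusted p = 0.000388) and removal of the GC trend -0.44 (adjusted p = 0.0415). Cdk2 and Cdk9 were not analysed here.

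Gene groups of macrophage function rose as deposited, and their medians stayed above 0 with the read totals. Of 14 tested alternatively activated macrophage genes, 12 rose and 2 fell, with Mgl2 at 4.34, Clec10a at 3.70 and Arg1, arginase 1, at 3.43. The list passed camera as higher (median 3.45, and 1.35 with the read totals; adjusted p = 0.0102, and adjusted p = 0.294 with an estimated correlation). Of 15 lysosome and phagocytosis genes, 13 rose and 2 fell, with the protease Ctsb going from 451 FPKM ± 18.7 to 8029 ± 1211 (SD, n = 3), a log2 fold change of 4.14. Lamp1, a lysosomal membrane protein, was at 3.66 and Hexa at 3.57 (median of the list 3.05, and 0.91 with the read totals; adjusted p = 0.00449, and adjusted p = 0.249 with an estimated correlation). Of 15 monocyte and macrophage markers, 13 rose and 2 fell, with Ms4a7 at 4.29, lysozyme gene Lyz2 at 3.65 and complement gene C1qb at 3.59 (median 2.88, and 0.71 with the read totals; adjusted p = 0.00449, and adjusted p = 0.249 with an estimated correlation). Of 10 MHC class I presentation genes, 9 rose and 0 fell, and 8 rose adjusted over the list alone. B2m was at 4.05, H2-K1 at 3.91 and H2-T23 at 3.5, and the H2 genes are close paralogs (median of the list 2.70, and 0.64 with the read totals; adjusted p = 0.0106, and adjusted p = 0.411 with an estimated correlation). With the read totals fewer members of these 4 lists were called higher, with 8 that rose and 2 that fell, 8 and 3, 7 and 4, and 4 and 1. Quantile normalization ended the calls of Arg1 (0.21, adjusted p = 0.302), Lamp1 (0.60, adjusted p = 0.0668), Lyz2 (0.01, adjusted p = 0.986) and B2m (0.81, adjusted p = 0.0645). It gives genes of equal rank equal values, so genes near the top in every library have little room to rise under it.

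Ribosomal protein genes, which have many processed pseudogenes, rose in 20 of 20 members as deposited, with Rpl4 at 2.31 and Rpl3 at 2.20. With the read totals 1 of the 20 was called higher, and Rpl4 and Rpl3 stood at 0.15 and 0.05 (median of the list 2.53, and 0.48 with the read totals; adjusted p = 0.000688, and adjusted p = 0.411 with an estimated correlation). Mitochondrially encoded genes rose in 10 of 10 members as deposited and in 5 of 10 with the read totals, beside a share of mitochondrial reads of 0.854% in NP@M and 1.89% in NP-D@M. Their median was 3.35, and 1.2 with the read totals, with mt-Co3 at 3.53 and mt-Co1 at 3.27 (adjusted p = 0.00832, and adjusted p = 0.411 with an estimated correlation). With quantile normalization none of these 6 higher lists passed camera, and Rpl4, Rpl3 and mt-Co1 turned to -0.38, -0.26 and -0.40.

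Stress, survival and ribosome assembly groups fell. Of 13 integrated stress and unfolded protein response genes, 10 fell and 2 rose, with Xbp1, Sesn2 (-3.86) and Herpud1 (-3.59) smallest in adjusted p (median -2.20, and -3.97 with the read totals; adjusted p = 0.0443, and adjusted p = 0.249 with an estimated correlation). Of 12 BCL2 family and apoptosis genes, 9 fell and 2 rose. The list's named members that fell were the survival genes Mcl1 and Bcl2l1 (-3.29) and the death-promoting gene Bid (-1.79). Its median was -1.29, and -2.94 with the read totals (adjusted p = 0.0443, and adjusted p = 0.249 with an estimated correlation). Of 11 ribosome biogenesis genes, 10 fell and 1 rose, with the nucleolar protein genes Nop56 at -2.39, Wdr43 at -1.93 and Nop58 at -1.19 (median -1.11, and -2.59 with the read totals; adjusted p = 0.0329, and adjusted p = 0.249 with an estimated correlation). Median scaling ended the call of the BCL2 list (adjusted p = 0.0631) and of the biogenesis list (0.0525), removal of the length trend ended that of the biogenesis list (0.134), and the BCL2 list lost its call without NP@M replicate 2 (0.0526). Over all alternatives the adjusted p ran from 0.00989 to 0.249 for the BCL2 list and from 0.0217 to 0.249 for the biogenesis list.

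The other groups did not pass camera as deposited, although most of their members were called gene by gene. Of 13 CDK, cyclin and CDK inhibitor genes, 10 fell and 3 rose (median -1.30, adjusted p = 0.104), with the inhibitor Cdkn1b at -2, the transcriptional kinase gene Cdk13 at -1.73 and its cyclin gene Ccnk at -1.47. Of 13 G1/S cell cycle genes, 9 fell and 4 rose (median -0.95, adjusted p = 0.243), with the licensing factor Cdt1 at -2.73, Ccne1 at -1.92 and Slbp at -1.57. Of 17 G2/M cell cycle genes, 13 fell and 4 rose (median -1.2, adjusted p = 0.102), with Cdc20 at -2.54, Aurka at -1.64 and Bub1b at -1.2. Of 14 p53 target genes, 11 fell and 3 rose (median -1.51, adjusted p = 0.059), with Sesn2, Btg2 (-2.93) and Cdkn1a lowest in adjusted p, and the list passed without NP@M replicate 2 (0.0469) or with the length trend removed (0.026), over a range from 0.026 to 0.249. Immediate early genes split into 9 that fell, 6 that rose and 2 not called (median -1.25, adjusted p = 0.256), with Klf6 at -3.71 and Egr2 at -3.36. With the read totals the medians of these 5 lists lay between -2.23 and -2.80, and 0 members rose while 10 to 15 fell in each.

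Inflammatory, interferon, MHC class II and checkpoint groups moved in both directions as deposited. Of 19 NF-kB and inflammatory cytokine genes, 9 rose, 6 fell and 4 were not called (median 0.78, adjusted p = 0.602), with the neutrophil-attracting chemokine Cxcl2 at 3.91 and the NF-kB inhibitor Tnfaip3 and subunit gene Nfkb1 at -3.23 and -2.10. Of 13 type I interferon response genes, 7 rose, 5 fell and 1 was not called, and 7 rose and 6 fell adjusted over the list alone (median 0.60, adjusted p = 0.801). Irf7 was at 3.94, Bst2 at 3.70 and Oasl1 at -1.67. Of 10 MHC class II and costimulation genes, 6 rose and 2 fell (median 1.21, adjusted p = 0.193), with Ctss at 3.72, H2-DMa at 2.19 and the costimulatory ligand gene Icosl at -1.82. Of 9 immune checkpoint genes, 5 rose and 3 fell (median 0.39, adjusted p = 0.777), with Lgals9 at 1.80, Pvr at 1.64 and Sirpa at -2.47, and Lgals9 and Pvr turned to -0.34 and -0.25 with the read totals. H2-DMa lost its call with the read totals (0.06, adjusted p = 0.88) and with quantile normalization (0.17, adjusted p = 0.605), as Ctss did with the latter (0.29, adjusted p = 0.144). Scaling to the read totals turned the medians of these 4 lists to -1.08, -1.04, -0.78 and -1.13, where 4 rose and 9 fell, 2 and 8, 1 and 4, and 0 and 6. Quantile normalization turned that of the NF-kB and checkpoint lists to -0.32 and -0.53. Of 10 T cell chemokines and myeloid chemokine receptors, 7 rose and 3 fell, with Ccl8 at 3.79 and Ccl2 at 3.60 beside Ccl12. Their median was 2.85 (adjusted p = 0.193), and 1.12 with the read totals, where 5 rose and 3 fell and the list passed (adjusted p = 0.00465, over a range from 0.00465 to 0.406).

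As deposited, metabolic groups split as well. They leaned lower with the read totals, with 3 that rose and 6 that fell in the NRF2 list (median -2.65), 0 and 6 in the glycolysis list (-2.15) and 1 and 8 in the cholesterol list (-1.73). Of 10 NRF2 and oxidative stress genes, 5 fell, 4 rose and 1 was not called, with Fth1 at 4.06, Prdx1 at 3.98 and Txnrd1 at -1.79. Quantile normalization put Fth1 at 0 (adjusted p = 1), as it must for a gene of the same rank in every library. This lost call therefore does not speak against the rise. The median of the NRF2 list, -0.67, and the test (lower, adjusted p = 0.964) differed in sign from its mean of 0.51. Of 10 glycolysis and hypoxia genes, 5 rose and 5 fell (median -0.39, adjusted p = 0.871), with hexokinase gene Hk2 at -3.26, Vegfa at -2.29 and Pgk1 at 2.08, which turned to -0.08 with the read totals. Of 9 cholesterol synthesis genes, 4 fell, 3 rose and 2 were not called (median -0.04, adjusted p = 0.871), with Hmgcs1 at -1.55, Sqle at -1.2 and Dhcr7 at 2.15. Median scaling turned the medians of the glycolysis and cholesterol lists to 0.11 and 0.37, and that of the cholesterol list turned to 0.21 with quantile normalization and to 0.77 with the length trend removed, where 5 rose and 4 fell. The glycolysis list instead passed as lower with quantile normalization (median -1.40, adjusted p = 0.00989, over a range from 0.00989 to 0.952).

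Of the marker lists of other cell types, only those of granulocytes and dendritic cells were large enough for camera, and neither passed as deposited. Of 14 neutrophil and granulocyte precursor markers, 5 rose, 4 fell and 5 were not called (median -0.44, adjusted p = 0.874), with the proteases Mmp8 at 2.82 and Mmp9 at 1.30 and the receptor Cxcr2 at -3.41. With the read totals the list's median was -2.33 and 12 fell, and Mmp9 stood at -0.86, while median scaling turned the median to 0.06. Quantile normalization gave a median of -1.43, and the list passed as lower (adjusted p = 0.0172, over a range from 0.0172 to 0.992). Mmp8 lost its call with the read totals (0.65, adjusted p = 0.107) and turned to -0.44 with quantile normalization, where Mmp9 stood at -1.33. Of 6 dendritic cell markers, 2 rose and 3 fell (median -0.20, adjusted p = 0.871, and 0.03 with quantile normalization), with Itgax at 2.91, Ccr7 at -2.94 and Fscn1 at -1.41, and quantile normalization ended the call of Itgax (0.32, adjusted p = 0.345). Of 3 tested erythroid and megakaryocyte markers, 3 rose, all of them platelet genes, Pf4, Ppbp (3.59) and Itga2b (1.02), and Itga2b turned to -0.74 with the read totals, while Ppbp lost its call with quantile normalization (0.66, adjusted p = 0.0582). Of 2 mast cell and basophil markers, Gata2 fell with a log2 fold change of -2.90 and Cpa3 was not called (0.48, adjusted p = 0.204, and -1.16 with the read totals), and Cpa3 passed as higher with quantile normalization (0.90), median scaling (0.89) and only the 6 samples compared (0.48). Both stromal and endothelial markers that were tested, Cdh5 (1.04) and Pecam1 (0.67), rose, as did the epithelial marker Cdh1 (1.71). Pecam1 was not called without NP@M replicate 1 (adjusted p = 0.0643) or NP-D@M replicate 2 (0.0599), over a range from 5.9e-05 to 0.0994, and Pecam1 and Cdh1 turned to -1.19 and -0.31 with the read totals, where Cdh5 lost its call (0.45, adjusted p = 0.0579). The single tested B and plasma cell marker was not called (0.49, and -0.38 with the length trend removed) and was called lower with the read totals (-1.18), and of the T and NK cell markers and the retina markers 0 passed the filter on low values.

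**Figure D3:**
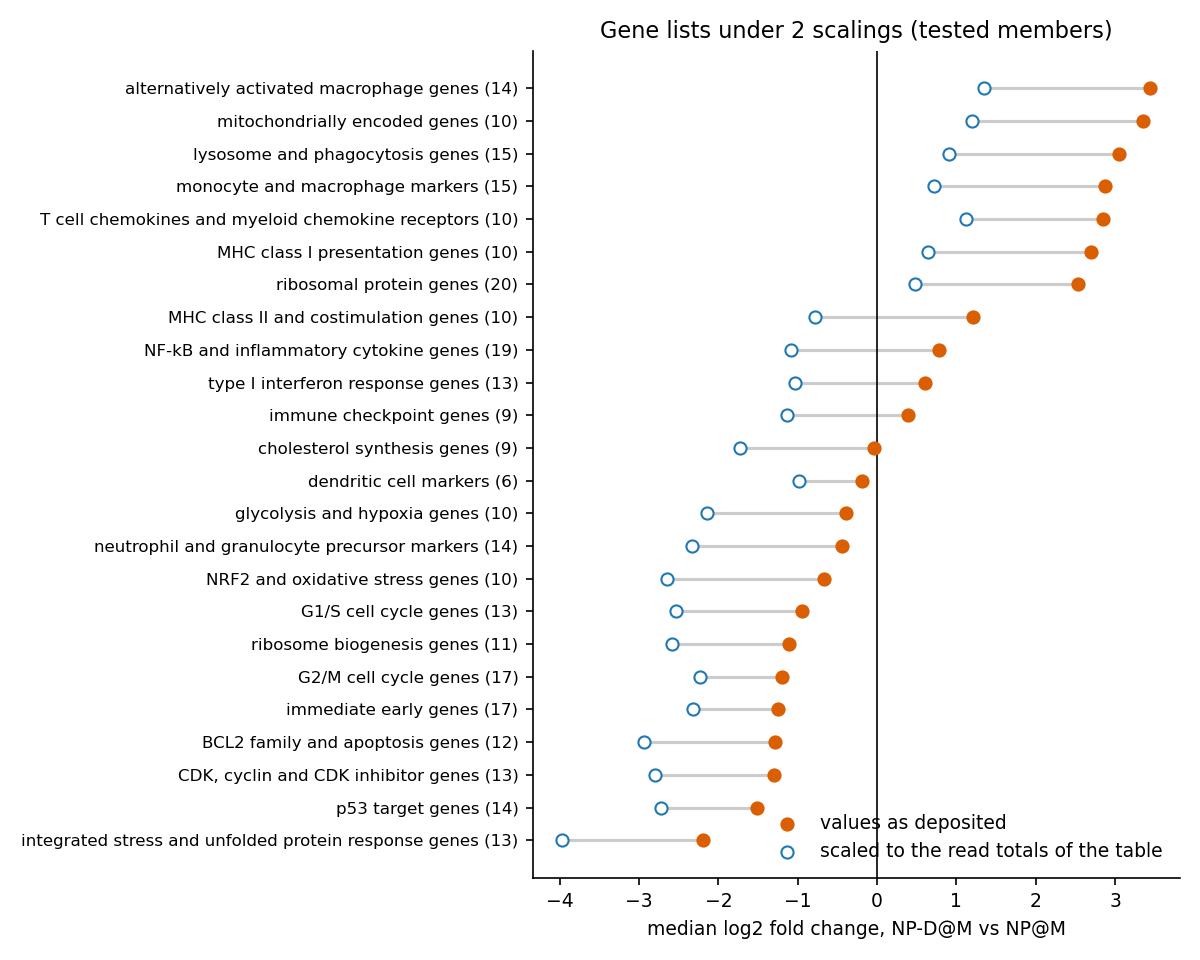
Median log2 fold change of each gene list with at least 5 tested members in NP-D@M against NP@M, with the deposited scaling as filled points and scaling to the read totals as open points, and the number of tested members in brackets. The order of the lists is alike, and the medians of the MHC class II, NF-kB, interferon and checkpoint lists cross 0.

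By limma, 3893 of 8615 tested genes were called higher and 3962 lower in NP-D@M, 91.2% of those tested, and 3116 rose and 3046 fell by at least 2-fold. The groups did not overlap in 8008 genes (93.0%, where chance gives 10% among genes not picked for a difference). The table appears picked for differences, so the gap to 10% is no measure of the effect. Camera called 6 lists higher and 3 lower, and 0 held with an estimated correlation, while the members called over all genes equalled those called adjusted over the list alone in every list but the interferon and MHC class I lists. Correlation alone does not account for each loss under that setting. The BCL2 list had an estimated correlation of -0.0095, below the preset 0.01, and its adjusted p by camera still went from 0.0443 to 0.249. With the read totals the median of all genes moved from 0.16 to -1.47 and the calls became 786 higher and 5313 lower. Of 5546 genes called with both scalings, 4748 had the same sign, and no external standard in the table fixes which scaling holds.

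The comparison of NP-D@MP with NP-D@M asks what differs with P in the name, and no gene passed the test over all genes. The members of the NF-kB and inflammatory cytokine list named here had lower values with P, none of them called over all genes as deposited. Il12b, a subunit of interleukin 12, stood at 6.52 FPKM ± 4.03 in NP-D@M and 0.546 ± 0.258 in NP-D@MP (SD, n = 3), a log2 fold change of -2.17 (SE 0.31, adjusted p = 0.0578, lower in 3 of 3 libraries). Il6 stood at 7.60 FPKM ± 2.09 and 2.54 ± 0.937 (log2 fold change -1.29, adjusted p = 0.136), and Ptgs2, the inducible prostaglandin synthase, at 13.5 ± 2.81 and 3.08 ± 1.10 (log2 fold change -1.84, adjusted p = 0.149). Il1b, named after its values were seen, had a log2 fold change of -2.45 (adjusted p = 0.149) and was called without NP-D@MP replicate 2 (-3.03, adjusted p = 0.0183, over a range from 0.0183 to 0.55).

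The NF-kB and inflammatory cytokine list was lower by camera, with a median of -0.66 over 19 members (adjusted p = 3.96e-15, and adjusted p = 0.0756 with an estimated correlation). Of its members, 0 were called over all genes and 7 were lower adjusted over the list alone. Neutrophil and granulocyte precursor markers were higher, with a median of 0.68 over 14 members (adjusted p = 6.4e-07, and adjusted p = 0.186 with an estimated correlation), and 0 were called over all genes against 7 higher adjusted over the list alone. Lactoferrin gene Ltf stood at 12.5 FPKM ± 2.69 in NP-D@M and 41.9 ± 11.5 in NP-D@MP (SD, n = 3), a log2 fold change of 1.65 (adjusted p = 0.136). Retnlg was at 2.01 (adjusted p = 0.149) and Ngp, a granule protein gene, at 1.55 (adjusted p = 0.316). Immediate early genes were lower with a median of -0.15 over 17 members, 0 of them called, with Dusp1 at -0.72 and Fos at -0.68 (adjusted p = 0.0424 for the list, and adjusted p = 0.655 with an estimated correlation). The immediate early list lost its call without NP-D@M replicate 1 (adjusted p = 0.769), NP-D@MP replicate 1 (0.155) or NP-D@MP replicate 2 (0.443), with quantile normalization (0.0595) and with the read totals (0.0535), over a range from 7.69e-05 to 0.769.

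**Figure D4:**
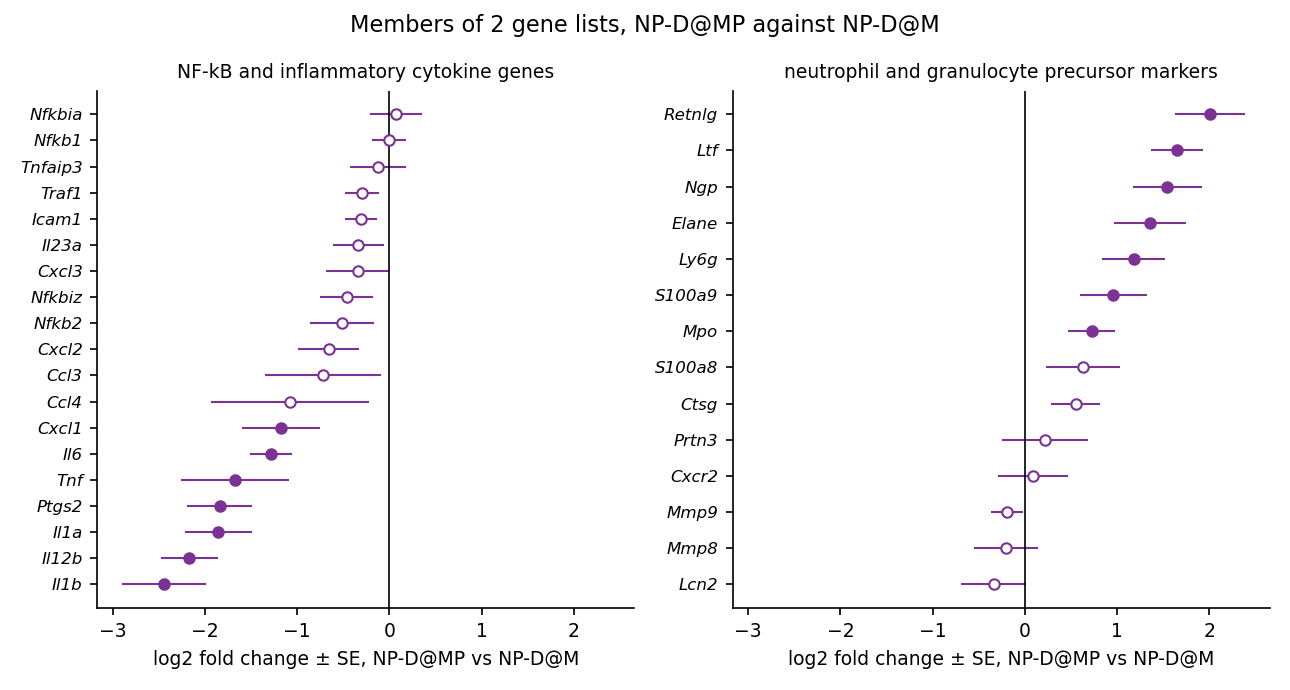
Log2 fold change with its SE for each tested member of the NF-kB and inflammatory cytokine list and of the neutrophil and granulocyte precursor list, NP-D@MP against NP-D@M, with 3 libraries per group. Filled points mark the 7 members of each list that passed adjusted over the list alone, lower in the cytokine list and higher in the granulocyte list, and 0 passed over all genes.

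Immune checkpoint genes had a median of -0.06 over 9 members and did not pass as deposited (adjusted p = 0.213), but passed as lower with the read totals (0.0166) and without NP-D@MP replicate 1 (0.0247), over a range from 0.0166 to 0.644. Mitochondrially encoded genes had a median of -0.23 over 10 members (adjusted p = 0.321) and passed as lower without NP-D@MP replicate 1 (2.68e-05), the library with 3.17% of its reads in them. Genes fixed for their link to CDKs and PD-L1 gave no call with P as deposited. Cd274 stood at 61.8 FPKM ± 3.39 in NP-D@M and 42.7 ± 2.21 in NP-D@MP (SD, n = 3), a log2 fold change of -0.52 (SE 0.26, adjusted p = 1, lower in 3 of 3 libraries). This SE pools the spread of all 12 libraries. Among them PBS replicate 3 (121 FPKM) and NP@M replicate 2 (110 FPKM) lay above their group mates. The missing call does not show that Cd274 is unchanged. Its lowest adjusted p by limma over the alternatives was 0.504. Pdcd1lg2 was at -0.42, Mcl1 at 0.08, Myc at -0.15, Cdk5 at 0.18, Cdk1 at 0.11, Cdkn1a at -0.10, Irf1 at 0.26 and Irf2bp2 at -0.02, each with an adjusted p of 1. Limma called 0 of 8615 genes, and 428 had an unadjusted p under 0.05, about as many as chance gives at that threshold. Voom on the recovered reads called 0, and limma without trend called 0. The groups did not overlap in 1268 genes (14.7%, where chance gives 10%). Calls appeared with median scaling (6), with no filter on low values (8), with a pseudocount of 0.1 (2), with the GC trend removed (1) and without NP-D@MP replicate 2 (4), and Il12b was among those with median scaling (adjusted p = 0.0247) and with no filter (adjusted p = 0.0426), over a range from 0.0247 to 0.762.

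The comparisons with PBS ask how NP-D@M and NP-D@MP differ from the vehicle, and in both most genes of the table differed. In NP-D@M, the chemokine gene Ccl12 rose by 5.41 (SE 0.41, adjusted p = 5.81e-07), Rn7sk by 6.45, Npy by 5.33, Pf4 by 5.10 and Mgl2, a macrophage lectin, by 4.68. Without PBS replicate 3, Npy rose by 4.65 and Pf4 by 4.44. Dusp6 fell with a log2 fold change of -5.49 (SE 0.21, adjusted p = 5.82e-08), Sgk1 with -5.31, Fpr1 with -5.09, Ptafr with -4.47 and Trib3 with -4.47 (-5.21 without PBS replicate 3). Mcl1 fell with -4.42, Myc with -3.07, Cdkn1a with -2.76, Irf2bp2 with -2.68, Irf1 with -2.24 and Pdcd1lg2 with -1.39. Cdk5 rose by 2.06 and stood at 0.12 with the read totals (adjusted p = 0.664), while Cdk1 (0.57) turned to -1.02 with that scaling. Cd274 was not called in NP-D@M against PBS (log2 fold change -0.39, SE 0.26, adjusted p = 0.175). Its values were -0.61 without PBS replicate 1 (adjusted p = 0.0481), -2.50 with the read totals (adjusted p = 2.93e-06), -2.39 with quantile normalization (adjusted p = 0.000459) and 0.14 with equal medians (adjusted p = 0.614), over a range from 2.93e-06 to 0.656.

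In NP-D@MP against PBS, Rn7sk rose by 6.99, Ccl12 by 6.02 (SE 0.41, adjusted p = 2.86e-07), Npy by 5.82, Pf4 by 5.38 and Rnase2a, a ribonuclease gene of leukocytes with close paralogs, by 4.92. Npy rose by 5.15 and Pf4 by 4.73 without PBS replicate 3. Sgk1 fell with a log2 fold change of -5.61, Fpr1 with -5.59, Dusp6 with -5.36, Hilpda, a lipid droplet gene induced by hypoxia, with -4.52 and the receptor gene Tlr2 with -4.50. Mcl1 fell with -4.34, Myc with -3.22, Cdkn1a with -2.86, Irf2bp2 with -2.70, Irf1 with -1.99 and Pdcd1lg2 with -1.81. Cdk5 rose by 2.24 and stood at 0.21 with the read totals (adjusted p = 0.443), where Cdk1 (0.69) turned to -0.99. Cd274 fell from 84.7 FPKM ± 32.0 to 42.7 ± 2.21 (SD, n = 3), a log2 fold change of -0.91 (SE 0.26, adjusted p = 0.00669), and was not called with median scaling (-0.41, adjusted p = 0.164, over a range from 4.61e-07 to 0.164). Whether the effect on Cd274 differed between NP-D@MP and NP-D@M is the comparison of those groups given before, in which it was not called.

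Ribosomal protein genes rose in 20 of 20 members as deposited in both comparisons with PBS (medians 2.43 and 2.74), and mitochondrially encoded genes in 10 of 10 (medians 3.39 and 3.24). Scaled to the read totals, these medians were 0.39 and 0.52 for the ribosomal protein genes and 1.28 and 1.02 for the mitochondrial genes. Of the ribosomal protein genes 1 then rose in each comparison and 2 fell in NP-D@MP, and of the mitochondrial genes 5 and 3 rose. Quantile normalization turned the ribosomal median to -0.03 in NP-D@M. By camera the lysosome, alternatively activated macrophage, MHC class I and monocyte and macrophage lists were also higher in both, the BCL2 family and ribosome biogenesis lists were lower in both, and the stress response (adjusted p = 0.0335) and p53 target lists (adjusted p = 0.048) were lower in NP-D@MP. Camera called 8 lists in NP-D@M and 10 in NP-D@MP, and 0 held with an estimated correlation (adjusted p from 0.247 to 0.402, and from 0.231 to 0.426, with an estimated correlation). In NP-D@M the stress response list had an adjusted p of 0.0583, and it passed with quantile normalization (0.0054), with the length trend removed (0.031), without PBS replicate 3 (0.0471), without NP-D@M replicate 1 (0.0488) and without both libraries that stood apart (0.0471). The p53 list, not called in NP-D@M (adjusted p = 0.0631), passed there without PBS replicate 3 (0.0471) or with the length trend removed (0.034). Whether these lists differ between NP-D@MP and NP-D@M was tested in the comparison of those groups, where neither was called. Quantile normalization also gave calls as lower to the glycolysis list (0.00842 in NP-D@M and 0.00383 in NP-D@MP), the immediate early list (0.0232 and 0.0129) and, in NP-D@M, the granulocyte list (0.0123). The T cell chemokine list passed as higher with the read totals (0.00645 and 0.0177), and the immediate early list passed as lower in NP-D@MP with the length trend removed (0.0325). The p53 list in NP-D@MP also lost its call with the read totals (adjusted p = 0.135, over a range from 0.0297 to 0.25). Quantile normalization ended the calls of the 6 higher lists in both comparisons, and those of the p53 (0.0841) and biogenesis (0.0548) lists in NP-D@MP. Median scaling ended those of the BCL2 and biogenesis lists in NP-D@M (0.0552 each), and removal of the length trend that of the biogenesis list in both (0.157 and 0.169). Of the lists that lost calls with 1 library out, the p53 list did so without NP-D@MP replicate 2 (0.0508), PBS replicate 1 (0.0624) or PBS replicate 2 (0.0545), and the BCL2 list in NP-D@M without NP-D@M replicate 2 (0.0502).

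Limma called 3840 genes higher and 3948 lower in NP-D@M against PBS and 3937 higher and 3945 lower in NP-D@MP against PBS, of 8615 tested. The groups did not overlap in 7768 genes (90.2%) and 7699 genes (89.4%), where chance gives 10%. Scaled to the read totals, the calls became 770 higher and 5311 lower in NP-D@M, and 776 higher and 5375 lower in NP-D@MP. Both comparisons share the PBS libraries, and in each only 6.73% and 6.27% of tested genes lay within 0.5 of 0, as 6.14% did in NP-D@M against NP@M, so the table appears to hold genes picked for a difference and the counts are no share of the genome.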

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

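Scaling to the read totals, removal of the length or GC trend, voom and leaving out both libraries that stood apart were chosen only after the data were seen. No paired analysis was possible because the replicate numbers give only the order of the records. Of 176 named gene results, 141 kept the same call and, where called, direction under every alternative run. Over all alternatives 38 values lost a call and 12 gained one without a turn, and 18 turned direction. For lists 88 lost, 32 gained and 3 turned. A result that turned was counted as a turn alone, whether or not it was called in the new direction. A turn was counted only for results called as deposited, under the alternative or both. Changes of sign in results called in neither, as for Cd274 in NP-D@M against NP@M with equal medians, are not counted. Counts of called genes in the 3 comparisons of D with no D stayed within 1.5 times the reported count except with the filter of 5, where fewer genes are tested: 4422 in NP-D@M against NP@M, 4388 in NP-D@M against PBS and 4447 in NP-D@MP against PBS. With 1 library left out they ran from 7461 to 7604, 7415 to 7620 and 7462 to 7761. In NP@M against PBS the count was 0 with quantile normalization, median scaling, no filter, the filter of 5, limma without trend, a pseudocount of 0.1, the length trend removed, the GC trend removed, voom, only the 6 samples compared and both libraries that stood apart left out, and ran from 0 to 1 with 1 library left out. In NP-D@MP against NP-D@M it was 6 with median scaling, 8 with no filter, 2 with a pseudocount of 0.1 and 1 with the GC trend removed, and ran from 0 to 4 with 1 library left out (the cause was not tested). The direction turned with the read totals, as a lower scale for libraries with D must do for small rises, in NP-D@M against NP@M for Pvr (-0.25), Lgals9 (-0.34), Pgk1 (-0.083), Mmp9 (-0.86), Itga2b (-0.74), Cpa3 (-1.16), Pecam1 (-1.19), Cdh1 (-0.31) and Cdk1 (-1.002), in NP-D@M against PBS for Cdk1 (-1.02), and in NP-D@MP against PBS for Cdk1 (-0.99). With quantile normalization it turned in NP-D@M against NP@M for Lgals9 (-0.29), Pgk1 (-0.59), Rpl4 (-0.38), Rpl3 (-0.26), mt-Co1 (-0.40), Mmp8 (-0.44) and Mmp9 (-1.33), and the ribosomal protein list turned in NP-D@MP against PBS (adjusted p = 0.911), and the cause was not tested. Of the genes that turned with quantile normalization, only Mmp9 was called in the new direction. Of those that turned with the read totals, Pvr, Lgals9, Pgk1 and Cdh1 were not called in it. In NP@M against PBS the immediate early list ran from an adjusted p of 0.000814 to 1 with 1 library left out and turned without NP@M replicate 2, and the lysosome list turned and was called with both libraries that stood apart left out (adjusted p = 0.0412), and the cause was not tested. Gm24366 has no value with the filter of 5. The recovered reads limit genes near 0, where 3 reads are the floor.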

Other observations

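Chosen only after the result was seen were the tests on gene types, on scaling, on the length trend in the groups, on correlation with the libraries with D and on abundant granulocyte markers, while leaving out single libraries was planned but read as a test of a single cause only then. Small nuclear RNA genes, which include the RNAs of the spliceosome, rose in 16 of 20 tested genes and fell in 1 in NP-D@M against NP@M, with a median log2 fold change of 2.95, 2.19 with the read totals, where again 16 rose and 1 fell, and 0.75 with the length trend removed, where 7 rose and 2 fell. Processed pseudogenes rose in 422 of 532 and fell in 33, with a median of 1.51, 0.28 with the read totals, where 69 rose and 63 fell, and turned to -0.22 with the length trend removed, where 89 rose and 137 fell, and reads of their parent genes can be counted in them. Long intergenic non-coding RNA genes rose in 53 of 74 and fell in 12 (median 1.2, 0.34 with the read totals, where 18 rose and 16 fell, and turned to -0.06 with the length trend removed, where 19 rose and 18 fell). Protein coding genes rose in 3253 of 7773 and fell in 3884 (median -0.58, -1.75 with the read totals, where 636 rose and 5186 fell, and -0.16 with the length trend removed, where 2913 rose and 3272 fell). Median gene lengths were 164 bases for the small nuclear RNA genes, 527 for the processed pseudogenes, 1243 for the long intergenic genes and 4114 for the protein coding genes.

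The libraries with D differed from those without over most of the table. A factor between libraries moves all genes in the same direction, and through the pseudocount it moves genes with low values less. Scaling as the whole cause of the differences between genes is thus argued against in NP-D@M against NP@M. There 3116 genes rose and 3046 fell by at least 2-fold. The interquartile range of log2 fold changes was 2.94 there and 0.17 in NP@M against PBS. It decides less, since a factor can widen it through the pseudocount and the table appears picked for differences. Gene length bias as the whole cause is argued against by 6579 calls with each library's length trend removed, although the median log2 fold change went from 1.75 in the shortest eighth of genes to -1.12 in the longest. The share of genes that rose stays open, since with the read totals 12.9% of called genes rose in place of 49.6%, and the table has no external standard. A loss of transcripts that turn over fast may contribute, a hypothesis whose test could have failed: the median of 421 transcription factor genes lay -0.37 from that of genes matched on length and level (-0.95, with 95% of matched sets from -1.04 to -0.86 and 0 of 10000 as low). The level was the mean over all libraries, those with D included. The matched sets measure spread between genes, not between libraries. Turnover itself was not measured, and transcription factor genes only stood in for such transcripts. Other lists that may hold such transcripts split as deposited. In the immediate early list 9 fell and 6 rose (adjusted p = 0.256 by camera), and in the NF-kB and inflammatory cytokine list 6 fell and 9 rose. With the read totals 11 fell and 0 rose in the former, and 9 fell and 4 rose in the latter.

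PBS replicate 3 and NP@M replicate 2 stood apart from their groups and correlated at 0.971 with each other across genes. RNA of the groups with D mixed into them is argued against by their correlations with the mean of the libraries with D, at most 0.583, against 0.724 to 0.749 for the other libraries without D. Gene length bias as the whole cause is argued against too, since removing the length trend closed 34.1% of the gap in within-group correlation (from 0.832 to 0.882, with other pairs at 0.978 or more). A part of the gap may lie in it, with the shortest eighth of genes at -0.46 and the longest at 0.62 against group mates in PBS replicate 3. Handling of these libraries together stays open, as the labels give no batch, and no biological explanation was tested.

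As lists, by camera with its preset correlation only, inflammatory cytokine genes were lower and granulocyte markers higher in NP-D@MP than in NP-D@M (adjusted p = 0.0756 and 0.186 with an estimated correlation), with 0 members of either called over all genes. A single library as the cause is argued against by the highest adjusted p of either list with 1 library left out, 0.000282. Gene length bias is argued against by the higher adjusted p of the lists with the length trend removed, 4.2e-07. More granulocytes among the cells may raise the markers, but of 6 abundant markers 3 were higher and 3 lower, with the lowest at -0.34 and a median of 0.22, which leaves this open. An effect of P on the cells is the design's own explanation and stays open as well, since neither list held with an estimated correlation.

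The 6 libraries of a comparison can be split in 10 ways, too few for a share under 0.05. In comparisons of D with no D, every split but the real one mixes both kinds of library in each part. That adds their difference to the spread, so few gene calls in those splits were set by the design and decide nothing about chance. As many calls of genes as the real split came from 1 split in NP@M against PBS (1 gene, highest other 0), 1 in NP-D@M against NP@M (7855, highest other 0), 10 in NP-D@MP against NP-D@M (0, highest other 4), 1 in NP-D@M against PBS (7788, highest other 0) and 1 in NP-D@MP against PBS (7882, highest other 0). For lists the splits with as many calls were 4 in NP@M against PBS (4 lists, highest other 5), 1 in NP-D@M against NP@M (9, highest other 8), 3 in NP-D@MP against NP-D@M (3, highest other 4), 2 in NP-D@M against PBS (8, highest other 9) and 1 in NP-D@MP against PBS (10, highest other 7).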
